A study of Rattus norvegicus with 4 samples.

How the data were processed

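Skeletal muscle RNA of rats of the F344/DuCrlCrlj strain was measured on 4 single-colour oligonucleotide arrays, 1 per group: sham, ischemia, ischemia with electrical stimulation (ES) and ischemia with exercise. The groups were taken from the titles and the group label of the samples. Which muscle was taken, how many animals stood behind an array, whether their RNA was pooled, and the protocol and timing of ES and exercise are not given in the sources used here. Per the labels' protocols, RNA was isolated with a column kit for fibrous tissue, and biotinylated cRNA was made with a kit that primes at the 3' end of transcripts.

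The authors deposited 1 intensity per probe set and array on a linear scale. MAS5 is named in the submitters' processing notes, without a version. The 2% trimmed mean of the deposited intensities was 150.1 on each of the 4 arrays, so each array had been brought to a common mean before deposit. Detection calls and scanner files were not used here. This scaling fixes the mean of each array, so a difference in the total amount of mRNA between samples cannot be seen, and MAS5 signals of dim probe sets are noisy. Of 31099 probe sets, 20832 had 1 gene symbol in the platform annotation of 2016, 436 had several and 9831 had none, among them 57 control probe sets. No gene was named from a probe set with several symbols. For 20764 of the 20832 the gene identifier was found in a RefSeq gene table (assembly GRCr8), and 0 symbols differed. The build behind the probe annotation was not used, so no coordinates are given.

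The intensities were rescaled to a common 2% trimmed mean, values under the 50th percentile of all values of the 4 arrays (a signal of 30.1) were set to that floor, and log2 was taken. Each gene was represented by its probe set with the highest mean signal. The 10092 genes above the floor on at least 1 array were compared. With 1 array per group no difference has a replicate check and no p-value was computed. A gene was counted as higher or lower where the ratio of the floored signals of 2 arrays reached 2-fold. A gene at the floor on 1 array of a comparison has only a bound, given as "at least". The number of arrays limits the precision of every value.

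Before the data were examined, 29 gene lists, the comparisons, the settings and the rule for named genes were fixed. The rule took, per comparison, the 10 highest and 10 lowest ratios among counted genes above the floor on both arrays, leaving out symbols that start with LOC or RGD. It also took up to 5 bounds per direction, up to 4 members per list past 2-fold, 10 fixed genes (Ppargc1a, Vegfa, Nos3, Hif1a, Myh7, Myh4, Mstn, Pdk4, Fos and Hspa1a), and all genes of an overlap of 5 or fewer. Genes whose other probe sets went another way are named with that fact. Mstn was at or under the floor on all 4 arrays and has no ratio. Genes named outside this rule are said to be so. Each list's median log2 ratio was set against the medians of 10000 random lists of the same size, matched in 20 bins of mean log2 signal. The percentile describes these arrays and is no test of the conditions. A list is said to stand apart under percentile 2.5 or over 97.5. Of 116 list medians (29 lists in 4 comparisons), 50 stood apart, where 5.8 would for lists of randomly drawn genes. Genes of 1 list may vary together and the comparisons share arrays, so 5.8 is no measure of chance for these lists. The lists held 365 measured genes, of which 5 stood in more than 1 list.

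The comparisons of ES and of exercise share the ischemia array. Unchanged arrays were therefore simulated in 100 draws with a single-array noise taken by signal bin from the ES and exercise arrays (median absolute deviation of their log2 ratio, scaled to an SD and divided by the square root of 2). This noise contains any real difference between those arrays, so a narrower noise, from the sham and exercise arrays, was added after seeing the data. That pair was used because it was the closest. Both noises were drawn from a normal distribution with the same SD on all arrays. The median absolute deviation gives little weight to the tails of the ratios, so unchanged arrays may give more calls than the simulated ones. The alternatives were quantile and cyclic loess normalization, a floor at the 30th or 70th percentile, a threshold of 1.5-fold or 3-fold, the mean of all probe sets of a gene, and leaving out the 504 probe sets marked as open to cross-hybridization. Counting only genes with no other probe set going the other way was added after seeing the data.

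The calculations were tested on simulated arrays for the comparison of ischemia with ES against ischemia, with 10000 genes compared. Their noise was taken from the sham and exercise arrays, the closest pair. Changed genes were drawn from genes outside the lists with signals over 4 times the floor. The rates below therefore do not cover dimmer changed genes or a wider noise. With the noise of the ES and exercise arrays, unchanged arrays gave 98.3 calls on average for this comparison. Of 100 genes changed 4-fold, 100% were recovered in the right direction, and of 100 changed 2.5-fold, 95.0%. Of 9452 unchanged genes outside the lists, 15 were counted as changed. A list shifted by 0.80 had a median of 0.73 at percentile 100, and 6 of 86 medians of unshifted lists stood apart. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the quantile and cyclic loess normalizations.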

Results

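Gene expression was measured in skeletal muscle of a rat model of intermittent claudication, the leg pain on walking that reduced blood flow causes. The 4 arrays covered sham, ischemia, ischemia with electrical stimulation of the muscle through its nerve (ES), and ischemia with exercise, with 1 array each. There were no replicates, so every difference below is a difference between 2 arrays with no replicate check. The arrays were alike in overall signal, with medians of 29.0 (sham), 29.3 (ischemia), 31.8 (ES) and 30.3 (exercise), and 49.3% to 51.1% of 31099 probe sets lay above the floor. The 18 hybridisation control probe sets, which are spiked in at fixed amounts, had a median SD of 0.06 in log2 signal over the 4 arrays. The actin 3' over 5' signal ratio, which grows as RNA degrades, was 4.38 for sham, 3.81 for ischemia, 5.94 for ES and 4.34 for exercise. The same ratio for GAPDH was 1.16, 1.04, 1.26 and 1.16 in that order. By count of genes past 2-fold, sham and exercise were the closest pair with 45 of 10092 genes, and sham and ES the most distant with 488.

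**Figure D1:**
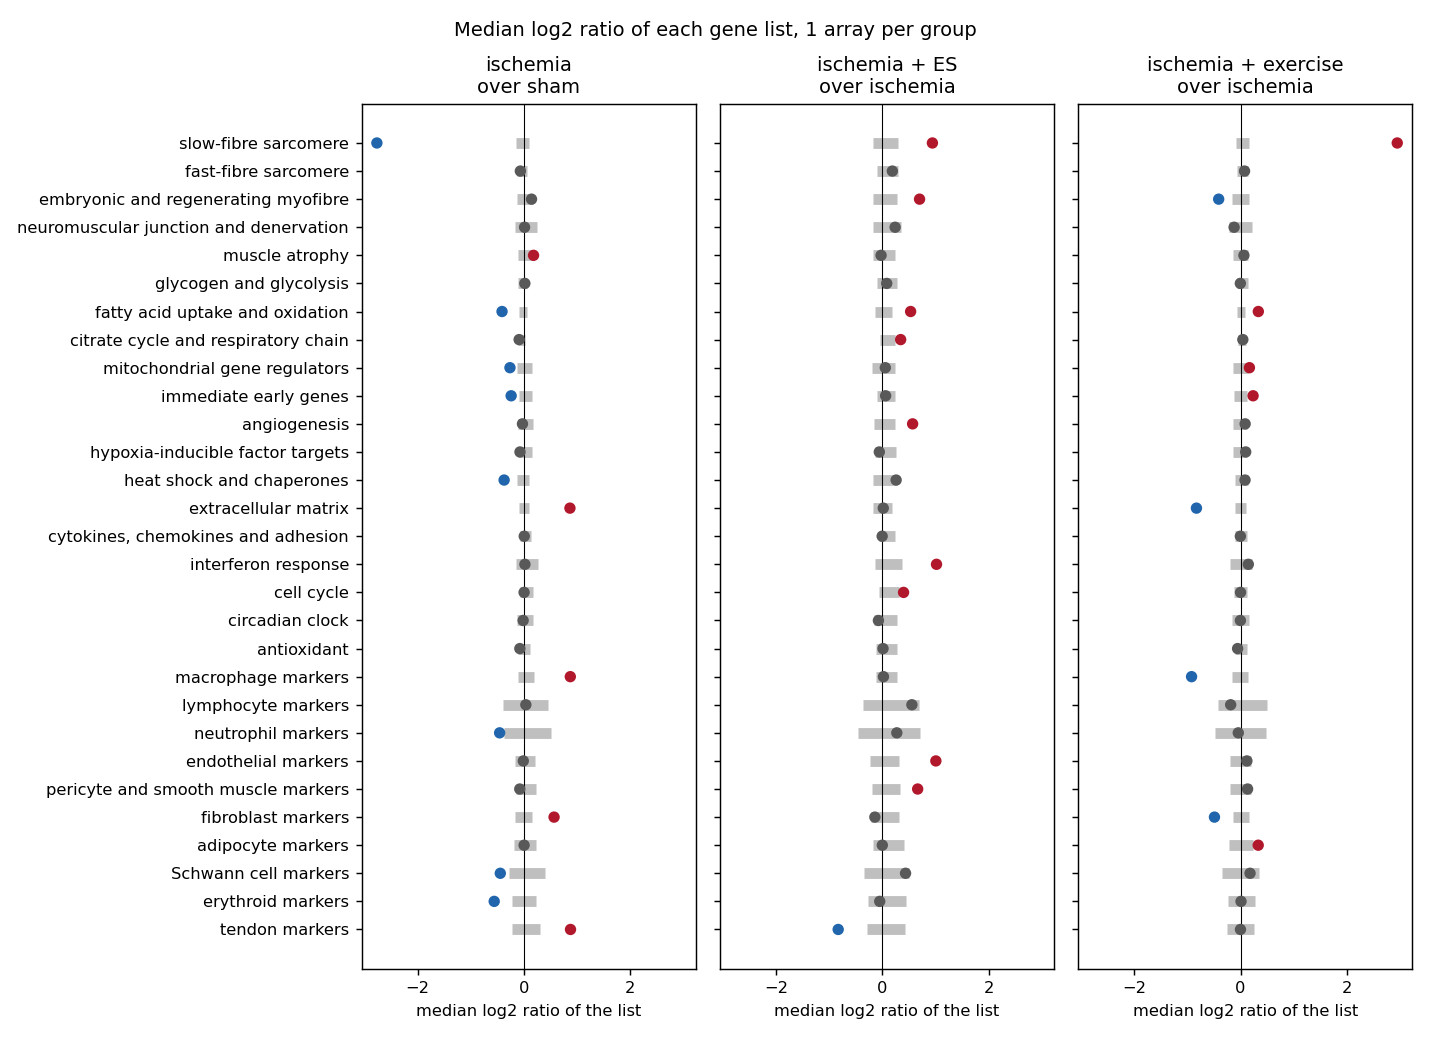
Each point is the median log2 ratio of a gene list (x axis) in 1 of 3 comparisons (panels), with 1 array per group; grey bars hold the middle 95% of medians of 10000 random lists of the same size and mean signal. Red points lie above percentile 97.5 and blue points below 2.5 of the random lists, and the slow-fibre list moves from -2.77 between ischemia and sham to 2.95 between exercise and ischemia.

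The ischemia array was compared with the sham array to ask what the ischemic muscle expressed differently. The list median of the slow-twitch contractile apparatus was lower with ischemia, and those of extracellular matrix and of macrophages were higher. All 10 measured slow-fibre genes were more than 2-fold lower, with a median log2 ratio of -2.77 at percentile 0 of the random lists. Myh7, the slow myosin heavy chain, was 3.82-fold lower, at a signal of 2970 against 11340, with its other probe set at a log2 ratio of -3.91. The slow troponin genes Tnnt1, Tnnc1 and Tnni1 were 9.92-fold, 7.58-fold and 7.09-fold lower, and Myoz2, a Z-disc protein of slow fibres, was 9.71-fold lower. Tpm3, which encodes slow tropomyosin, was 23.5-fold lower on its brightest probe set, but its 5 other probe sets above the floor had log2 ratios between -0.67 and 0.07. The fast-fibre list did not move with it: none of its 14 measured genes passed 2-fold, its median was -0.07 (0.01 under quantile normalization), and the fast myosin gene Myh4 was 1.03-fold higher.

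Outside that list, Sln, encoding sarcolipin, an inhibitor of the calcium pump, was 20.8-fold lower with ischemia, and Ankrd2, a stretch-responsive gene of slow muscle, was 15.6-fold lower. Rrad was 9.36-fold lower, Xpo4 7.55-fold and Fhl2 6.65-fold. Other probe sets gave smaller differences, with log2 ratios of -1.28 and -1.27 for Xpo4 and -1.78 for Fhl2. Genes at the floor with ischemia were Cda (at least 6.19-fold lower), Mmp13 (4.36-fold), Prox1 (4.31-fold), Ibsp (3.60-fold) and Eps8l2 (3.37-fold), each a lower bound. Immediate early genes, the first transcribed after a stimulus, had a median of -0.24 at percentile 0, and 4 of 18 passed 2-fold: Fos was 5.64-fold lower, Atf3 3.87-fold, Dusp1 2.0-fold (other probe set -0.51 in log2 ratio) and Nr4a2 at least 2.30-fold. Heat shock and chaperone genes had a median of -0.38 at percentile 0, with Hspb7 4.62-fold (other probe set -0.68 in log2 ratio) and Hspa1a 2.51-fold lower and the other 11 within 2-fold. Of 24 genes of fatty acid uptake and oxidation, 22 had a ratio below 0 and the median was -0.42 at percentile 0, but Lpl alone, the lipase that frees fatty acids from circulating lipoproteins, passed 2-fold (2.32-fold lower). Mitochondrial gene regulators had a median of -0.27 at percentile 0.04 with none of 14 past 2-fold, and Ppargc1a, the coactivator of mitochondrial genes, was 1.23-fold lower.

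On the higher side, 7 of 21 extracellular matrix genes were more than 2-fold higher with ischemia and none lower, with a median of 0.86 at percentile 100. Lox, which crosslinks collagen, was 3.62-fold higher, Col1a1 3.13-fold, Tnc 3.10-fold and Postn 2.96-fold. Macrophage markers had a median of 0.87 at percentile 100, with 7 of 18 past 2-fold, among them Gpnmb (7.50-fold higher), Cd68 (3.51-fold), Lyz2 (2.24-fold) and Adgre1 (2.20-fold). Fibroblast markers had a median of 0.56 at percentile 100 with Thy1 2.14-fold higher and the other 8 within 2-fold, and tendon markers a median of 0.87 at percentile 100 with Tnmd 2.42-fold higher and the other 5 within 2-fold. The highest ratio was that of Ankrd1, a muscle stress gene, at 10.6-fold. Mnda, a gene of myeloid cells, was 4.24-fold higher, Sfrp2, a secreted Wnt modulator, 3.96-fold, Cthrc1 3.75-fold and Apoe 3.07-fold. Genes at the floor in sham were Dnm2 (at least 2.81-fold higher), the chemokine gene Ccl2 (2.54-fold), Srpx2 (2.32-fold), Tmem45b (2.24-fold) and Fcgr2b (2.18-fold), each a lower bound. With Ankrd1 and Myh8 (2.34-fold) higher, the embryonic and regenerating myofibre list had a median of 0.14 at percentile 95.5, which did not stand apart.

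Other lists moved less between ischemia and sham. The muscle atrophy list had a median of 0.18 at percentile 98.9 with none of 14 genes past 2-fold. Schwann cell markers (4 measured) had a median of -0.45 at percentile 0.48, erythroid markers (3 measured) of -0.56 at percentile 0.14 and neutrophil markers (2 measured) of -0.46 at percentile 1.09, with no member past 2-fold. No list median stood apart for hypoxia-inducible factor targets (-0.08), angiogenesis (-0.03), glycogen and glycolysis (0.01), the citrate cycle and respiratory chain (-0.09), antioxidant genes (-0.08, under quantile normalization 0.01), the circadian clock (-0.02), the neuromuscular junction (0.01, under quantile and loess normalization -0.01) or the interferon response (0.02). The same held for endothelial markers (-0.02), pericyte and smooth muscle markers (-0.08) and lymphocyte markers (0.03, 2 measured), and the medians of the cytokine, cell cycle and adipocyte lists were 0.00. Single members past 2-fold in these lists were Chrnd (2.36-fold lower), Fgf1 (2.09-fold lower), Rsad2 (2.09-fold lower), Myh11 (2.12-fold lower) and Ccl2. The medians of 0.00 were set by genes at the floor and do not show unchanged expression. Only 2 of 10 cytokine, 6 of 15 cell cycle and 5 of 7 adipocyte genes lay above the floor on sham. Of the cytokine genes 5 had ratios above 0 and 0 below. With a floor at the 30th percentile their median was 0.40 and stood apart. Vegfa was 1.29-fold lower and Nos3 1.04-fold lower, while Hif1a was 1.17-fold and Pdk4 1.60-fold higher. In all, 79 genes were higher and 87 lower with ischemia, where 2 simulated unchanged arrays gave 102 calls on average with the wider noise and 16.0 with the narrower. Across the floors and fold thresholds tried, the counts ran from 11 to 499 higher and from 32 to 322 lower.

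**Figure D2:**
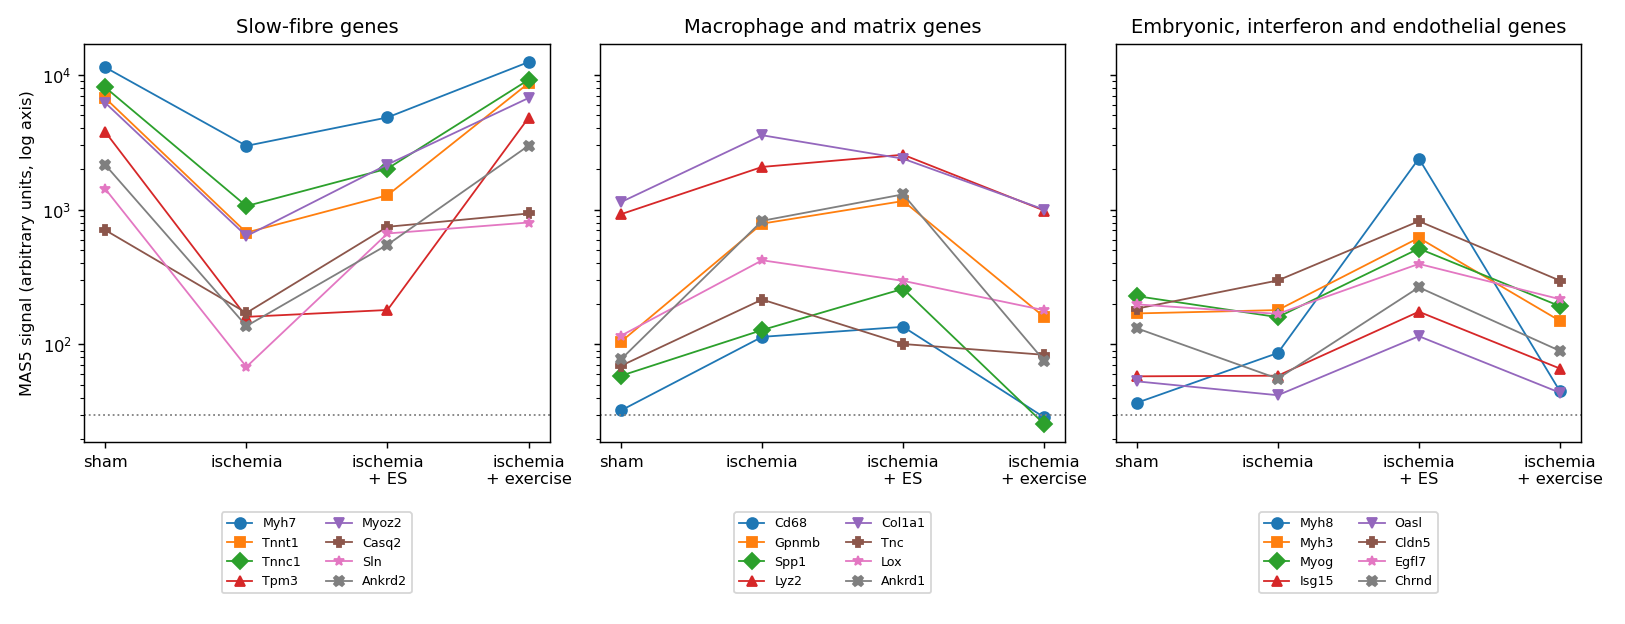
MAS5 signal of single genes (log axis, arbitrary units) on the 4 arrays (x axis), 1 array per group, with lines joining the values of a gene and a dotted line at the floor of 30.1. The slow-fibre genes shown, with Sln and Ankrd2, dip with ischemia and are back with exercise (Myh7: 2970 and 12422). The macrophage and matrix genes shown, with Ankrd1, are high with ischemia and lower with exercise, and Myh8 reaches 2393 with ES.

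Next, the ES array was compared with the ischemia array, since the study asked which expression differences the stimulated muscle shares with exercise. The list medians of developing and regenerating fibres, the interferon response and blood vessels were higher with ES, as was that of the slow-fibre genes, while those of oxidative metabolism differed less, with 1 of 24 fatty acid genes and 1 of 28 genes of the citrate cycle and respiratory chain past 2-fold. Myh8, the perinatal myosin heavy chain, had the highest ratio at 27.7-fold (signal 2393 against 86.4). The embryonic list had a median of 0.70 at percentile 100, and 5 of 13 genes passed 2-fold, among them the embryonic myosin gene Myh3 (3.43-fold higher), the myogenic transcription factor gene Myog (3.23-fold) and Tnnt2 (3.0-fold). Of the acetylcholine receptor genes, Chrnd was 4.76-fold and Chrna1 2.33-fold higher, although the neuromuscular junction and denervation list as a whole did not stand apart (median 0.24, percentile 89.3). All 10 slow-fibre genes had ratios above 0, with a median of 0.94 at percentile 100, and 4 passed 2-fold: Casq2 (4.35-fold higher), Myoz2 (3.39-fold), Myl2 (2.47-fold) and Tnni1 (2.28-fold). Myh7 was 1.62-fold higher (other probe set 0.11 in log2 ratio) and Myh4 1.27-fold lower, and none of 14 fast-fibre genes passed 2-fold (median 0.19, under quantile normalization -0.001).

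The medians of the vessel lists were higher with ES. Endothelial markers had a median of 1.01 at percentile 100, with 5 of 9 past 2-fold, among them the tight junction gene Cldn5 (2.75-fold higher), Egfl7 (2.35-fold), Emcn (2.20-fold) and Pecam1 (2.08-fold). Pericyte and smooth muscle markers had a median of 0.67 at percentile 100, but they did not all go one way: Mcam was 2.51-fold (other probe set 0.76 in log2 ratio) and Myh11 2.06-fold higher while Lmod1 was 2.34-fold lower. The angiogenesis list had a median of 0.57 at percentile 100, with the apelin receptor gene Aplnr 2.86-fold, Cxcr4 2.77-fold and Apln 2.10-fold (other probe set 0.47 in log2 ratio) higher, and 15 of 18 genes within 2-fold. Vegfa was 1.51-fold higher and Nos3, the endothelial nitric oxide synthase, 1.91-fold higher. Gpihbp1, which carries lipoprotein lipase across capillary walls, was 4.40-fold higher. Of 13 interferon response genes 7 were more than 2-fold higher, with a median of 1.02 at percentile 100, among them Isg15 (2.98-fold), Oasl (2.74-fold), Oas1a (2.59-fold) and Usp18 (2.49-fold). The actin 3' over 5' ratio was also highest on the ES array, and the median of all genes lay at 0.05.

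Metabolic lists moved by smaller amounts with ES. All 24 genes of fatty acid uptake and oxidation and all 28 of the citrate cycle and respiratory chain had ratios above 0, with medians of 0.53 at percentile 100 and 0.35 at percentile 99.98 (0.21 under quantile normalization), while only Fabp3 (2.10-fold) and Cox7a1 (2.89-fold) passed 2-fold. The cell cycle list had a median of 0.40 at percentile 99.6, with the proliferation marker Mki67 2.13-fold higher and the other 14 genes within 2-fold. Ppargc1a was 1.34-fold and Pdk4 1.47-fold higher, Hif1a was 1.07-fold lower, and mitochondrial gene regulators had a median of 0.06 with Prkaa2, an AMP-activated kinase subunit, 2.01-fold lower. Extracellular matrix genes did not stand apart from random lists with ES (median 0.02, under quantile normalization -0.003), although the basement membrane genes Col4a2 and Col4a1 were 2.86-fold and 2.06-fold higher and Tnc 2.14-fold lower. Macrophage markers did not either (median 0.02), with Spp1 2.02-fold higher and C1qb 2.08-fold lower. Tendon markers had a median of -0.83 at percentile 0, with Tnmd 3.09-fold, Fmod 2.90-fold and Chad at least 2.26-fold lower.

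Among other genes higher with ES were Sln (9.76-fold), the tissue kallikrein gene Klk1 (6.63-fold), the muscle LIM protein gene Csrp3 (5.02-fold) and Ankrd2 (4.01-fold). Ints1 was 6.88-fold higher, but its other probe set had a log2 ratio of 0.31, and Hspb7 was 3.59-fold higher while its other probe set was at -0.04. Genes at the floor with ischemia were Hpdl (at least 5.24-fold higher), Btnl9 (3.14-fold), Rad54l2 (3.0-fold), Pcdh17 (2.95-fold) and Klhl4 (2.86-fold), each a lower bound. Among named genes above the floor on both arrays, the lowest ratio was that of Cish, an inhibitor of cytokine receptor signalling, at 5.87-fold lower. It was followed by Tmem100 (3.78-fold lower), Mss51 (3.66-fold), Prkag3 (3.31-fold), Ttc7a (3.12-fold) and Dyrk2 (3.11-fold). Next came Tnmd (3.09-fold), Gpcpd1 (3.06-fold, other probe set -0.27 in log2 ratio), Mllt3 (2.94-fold) and the sodium pump subunit gene Atp1b2 (2.91-fold, other probe set -0.67). Genes at the floor with ES were Adgrb2 (at least 4.99-fold lower), Tsn (2.79-fold), Chad, Cyp1b1 (2.16-fold) and P4ha3 (2.15-fold), again as lower bounds. Lists that did not stand apart were muscle atrophy (-0.02), glycogen and glycolysis (0.08, under quantile normalization -0.10), hypoxia-inducible factor targets (-0.06), antioxidant genes (0.01, under quantile -0.03), cytokines (0.00), immediate early genes (0.06), the circadian clock (-0.07), heat shock (0.26 at percentile 96.9, but apart under quantile and loess normalization, both other floors and the mean of probe sets), and fibroblast (-0.14), lymphocyte (0.56), neutrophil (0.27), adipocyte (0.00), Schwann cell (0.44) and erythroid markers (-0.05). Within them Junb (2.02-fold), Dbp (3.12-fold), Lck (2.03-fold), and with bounds Ccl5 (at least 2.71-fold) and Cidea (at least 2.18-fold) were higher. Fos was 1.11-fold lower and Hspa1a 1.18-fold higher. In all, 230 genes were higher and 80 lower with ES, against 98.3 calls on average between simulated unchanged arrays with the wider noise and 16.3 with the narrower. Across the floors and thresholds the counts ran from 25 to 989 higher and from 9 to 476 lower.

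The exercise array was compared with the ischemia array in the same way. The median of the slow-fibre list was higher with exercise, and those of matrix and macrophage genes were lower. All 10 slow-fibre genes were more than 2-fold higher, with a median of 2.95 at percentile 100: Tnnt1 was 12.8-fold, Myoz2 10.6-fold, Tnnc1 8.64-fold, Tnni1 8.63-fold and Myh7 4.18-fold higher, the other probe set of Myh7 at a log2 ratio of 4.02. Tpm3 was 29.9-fold higher on its brightest probe set, while its 6 other probe sets above the floor had log2 ratios between 0.01 and 0.81. Of genes outside the list, Ankrd2 was 21.8-fold, Rrad 18.0-fold, Sln 11.8-fold, Xpo4 11.4-fold and Fhl2 11.2-fold higher. Other probe sets gave smaller log2 ratios, 1.74 and 1.88 for Xpo4 and 2.24 for Fhl2. Myh4 was 1.01-fold higher (a log2 ratio of 0.02, under loess normalization -0.03), and none of 14 fast-fibre genes passed 2-fold (median 0.08). Genes at the floor with ischemia were Cda (at least 8.42-fold higher), Prox1 (7.46-fold), Eps8l2 (4.53-fold), Vtcn1 (3.76-fold) and Colq (3.49-fold), each a lower bound.

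Macrophage markers had a median of -0.92 at percentile 0 with exercise against ischemia, and 7 of 18 were more than 2-fold lower, among them Gpnmb (4.92-fold) and Adgre1 (2.53-fold), with bounds of at least 4.24-fold for Spp1 and 3.78-fold for Cd68. Matrix genes had a median of -0.83 at percentile 0, with 7 of 21 past 2-fold, all lower: Col1a1 was 3.56-fold, Tnc 2.57-fold, Col1a2 2.39-fold and Lox 2.35-fold lower. Fibroblast markers had a median of -0.49 at percentile 0, with Thy1 2.03-fold lower and the other 8 within 2-fold. The embryonic list had a median of -0.41 at percentile 0, with Ankrd1 10.9-fold and the cell cycle inhibitor gene Cdkn1c 2.60-fold lower and the other 11 within 2-fold. Cthrc1 was 3.98-fold lower, Cish 3.58-fold, Col6a2 3.43-fold (other probe set -0.76 in log2 ratio), the phagocyte oxidase gene Cybb 2.91-fold, Col14a1 2.84-fold (other probe set -0.78), Sfrp4 2.82-fold and Gadd45g 2.76-fold. Bounds stood for Sfrp2 (at least 5.44-fold lower), Rpl39 (3.57-fold), Aldh1l2 (3.51-fold) and Ccl2 (2.54-fold), which were at the floor with exercise.

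Immediate early genes had a median of 0.24 at percentile 99.9 with exercise, and Atf3 (4.22-fold), Fos (2.34-fold) and Egr1 (2.34-fold) were higher. Nr4a3 was 5.26-fold higher, but its 2 other probe sets had log2 ratios of -0.06 and 1.70. Hspb7 was 5.73-fold (other probe set 0.89 in log2 ratio) and Hspa1a 3.28-fold higher, although the heat shock list did not stand apart (0.09). Fatty acid genes had a median of 0.33 at percentile 100, with 23 of 24 above 0 and Lpl 2.19-fold higher. Mitochondrial gene regulators had a median of 0.17 at percentile 98.9 with none of 14 past 2-fold, and Ppargc1a was 1.87-fold higher; with a floor at the 70th percentile this list no longer stood apart. Adipocyte markers (7 measured) had a median of 0.33 at percentile 99.3, which was lost with the same floor, with Adipoq 3.07-fold and Cidea at least 2.71-fold higher. Vegfa was 1.37-fold, Pdk4 1.28-fold and Hif1a 1.05-fold higher and Nos3 1.05-fold lower. Lists that did not stand apart were endothelial (0.12), pericyte (0.13), lymphocyte (-0.19), neutrophil (-0.04), Schwann cell (0.18), erythroid (0.01, under quantile normalization -0.07 and loess -0.03) and tendon markers (0.00), the neuromuscular junction (-0.12), muscle atrophy (0.06), glycogen and glycolysis (0.00), the citrate cycle and respiratory chain (0.04, under quantile -0.05), angiogenesis (0.09, with Fgf1 2.66-fold higher), hypoxia-inducible factor targets (0.10), cytokines (0.00), the interferon response (0.15), the cell cycle (0.00), the circadian clock (0.00, with Dbp 2.52-fold higher) and antioxidant genes (-0.05). The cytokine and cell cycle medians were again held near 0 by genes at the floor. Of 10 cytokine genes 5 had ratios below 0 and 1 above. With a floor at the 30th percentile their median was -0.33 and stood apart. In all, 115 genes were higher and 88 lower with exercise, where simulated unchanged arrays gave 101 calls on average with the wider noise and 15.7 with the narrower. Across the floors and thresholds the counts ran from 43 to 406 higher and from 11 to 428 lower.

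ES and exercise were then compared directly. The medians of the developmental, matrix, macrophage and vessel lists were higher with ES, and those of the slow-fibre and immediate early lists were lower, with the members past 2-fold counted below. Of 13 embryonic list genes 9 were more than 2-fold higher with ES, with a median of 1.43 at percentile 100: Myh8 was 53.2-fold, Ankrd1 17.1-fold, Cdkn1c 4.85-fold and Myh3 4.13-fold higher. Macrophage markers had a median of 0.97 at percentile 100 and 8 of 18 past 2-fold, with Gpnmb 7.25-fold and Lyz2 2.59-fold higher and bounds of at least 8.59-fold for Spp1 and 4.49-fold for Cd68. Matrix genes had a median of 0.88 at percentile 100, with 8 of 21 past 2-fold higher and 1 lower: Col4a2 3.59-fold, Col6a1 2.90-fold and Col4a1 2.82-fold higher, and Ccn2 2.91-fold lower. Endothelial markers (0.87, percentile 100, 2 of 9 past 2-fold higher), angiogenesis genes (0.54, percentile 100, 4 of 18 higher and 1 lower), pericyte and smooth muscle markers (0.55, percentile 99.9, 0 of 11 higher and 1 lower) and interferon response genes (0.88, percentile 100, 4 of 13 higher) also had higher medians with ES. Among them Cldn5 was 2.76-fold, Aplnr 2.80-fold, Nrp1 2.13-fold (other probe set 0.50 in log2 ratio), Kdr 2.11-fold, Nos3 2.01-fold, Isg15 2.64-fold, Oasl 2.62-fold, Rsad2 2.5-fold and Usp18 2.10-fold higher, while Lmod1 was 2.84-fold and Fgf1 2.01-fold lower. Slow-fibre genes had a median of -1.78 at percentile 0, with 8 of 10 past 2-fold: Tnnt1 was 6.78-fold, Tnnc1 4.56-fold, Atp2a2 4.10-fold and Myh7 2.57-fold (other probe set -3.90 in log2 ratio) lower with ES, and Tpm3 26.6-fold lower on its brightest probe set, with the 6 others between -0.72 and -0.01 in log2 ratio.

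Immediate early genes had a median of -0.19 at percentile 0.41 between ES and exercise and 4 of 18 past 2-fold, with Atf3 2.78-fold, Fos 2.60-fold and Egr1 2.08-fold lower with ES and Nr4a3 at least 7.50-fold lower, its other probe sets at -2.10 and -0.08. Tendon markers had a median of -1.01 at percentile 0, with 3 of 6 past 2-fold: Chad was at least 3.25-fold, Scx 2.48-fold and Fmod 2.24-fold lower with ES. Adipocyte markers had a median of -0.34 at percentile 0.31, with Adipoq 3.89-fold lower and the other 6 within 2-fold. Hypoxia-inducible factor targets had a median of -0.18 at percentile 0.97, but the members past 2-fold went both ways: Ddit4 was 2.20-fold and Adm 2.04-fold higher, and Ankrd37 2.16-fold lower. Fatty acid genes (0.24, percentile 99.95), the citrate cycle and respiratory chain (0.32, percentile 100, Cox7a1 2.14-fold higher), the cell cycle (0.40, percentile 99.5, Mcm6 2.01-fold and Mki67 at least 2.86-fold higher) and the neuromuscular junction and denervation list (0.37, percentile 98.3, Chrnd 2.96-fold and Gadd45a 2.5-fold higher) had higher medians with ES. Cytokines (0.27, percentile 98.7, with bounds of at least 2.71-fold for Ccl5 and 2.33-fold for Ccl2) and lymphocyte markers (0.74, percentile 97.6, 2 measured, Lck 2.37-fold higher) stood apart, but not under quantile normalization. Not apart were fast-fibre genes (0.05, under quantile -0.04), muscle atrophy (-0.10), glycogen and glycolysis (0.08), mitochondrial gene regulators (-0.19), heat shock (-0.11, Hspa1a 2.78-fold lower), the circadian clock (-0.06), antioxidant genes (0.10, Nqo1 2.22-fold lower), and fibroblast (0.25, Thy1 2.44-fold higher), neutrophil (0.31), Schwann cell (0.38) and erythroid markers (-0.06).

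Further genes higher with ES than with exercise were the sodium pump family gene Atp1b4 (6.84-fold), Gpihbp1 (4.69-fold), Ccdc125 (4.44-fold), the fatty acid binding protein gene Fabp5 (4.40-fold) and Hpdl (3.90-fold). With exercise at the floor, Klk1 was at least 8.0-fold, Mmp12 4.86-fold and Igsf1 3.96-fold (other probe set 0.51 in log2 ratio) higher. Genes lower with ES were Xpo4 (8.79-fold), Rrad (7.53-fold), Fhl2 (6.0-fold), Ankrd2 (5.43-fold), Slc38a1 (4.8-fold) and Prox1 (4.57-fold). Other probe sets had log2 ratios of -1.09 and -1.88 for Xpo4, -2.24 for Fhl2 and -1.42 for Slc38a1. With ES at the floor, Cda was at least 8.42-fold, Slc4a3 5.06-fold, Adgrb2 4.65-fold and Vtcn1 3.76-fold lower. Ppargc1a was 1.40-fold, Myh4 1.29-fold and Hif1a 1.12-fold lower with ES, Pdk4 1.14-fold higher, and Vegfa 1.10-fold higher with its other probe set at -0.03. In all, 298 genes were higher and 111 lower with ES, against 101 calls on average between simulated unchanged arrays with the wider noise and 15.9 with the narrower. Across the floors and thresholds the counts ran from 40 to 1057 higher and from 27 to 464 lower.

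Genes that moved back toward sham were counted next. Of the 166 genes past 2-fold between ischemia and sham, 108 were past 2-fold in the opposite direction between exercise and ischemia. These were 65 of the 87 genes lower with ischemia and 43 of the 79 genes higher with it. On the exercise array 76 of those 87 and 77 of those 79 lay within 2-fold of sham. With ES 37 of the 166 moved back, 28 of the 87 and 9 of the 79, and 44 of the 87 and 30 of the 79 lay within 2-fold of sham. Because these counts share the ischemia array, chance gives opposite calls: simulated unchanged arrays gave 19.2 for exercise (at most 32) and 19.2 for ES (at most 31) with the wider noise, and 3.90 and 3.88 (at most 8 and 9) with the narrower. Independent lists would share 1.68 and 2.61 genes. The narrower noise is the spread between sham and exercise itself, so for exercise it is no separate measure of a return toward sham. Part of the excess may come from the shared array.

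Between both treatments, 34 genes were higher than ischemia with ES and with exercise, of which 21 had been lower with ischemia than with sham. They included Sln, Ankrd2, Rrad, Csrp3, Casq2, Myoz2, Myl2, Tnni1, Hspb7, Ints1 and Dbp, a clock-controlled transcription factor gene. Independent lists would share 2.62 genes, and simulated arrays shared 4.06 on average (at most 10) with the wider noise and 0.23 (at most 2) with the narrower. The 9 genes lower with both were Cish, Gadd45g, Sfrp2, Sfrp4, Tnc, Mnda, Rpl39, Ikbip and Tubb1, the last 2 named after their values were seen. This count was below the 15.0 of the simulation with the wider noise (at most 24), reached the highest draw of 9 with the narrower (mean 3.93), and stood against 0.70 for independent lists. Past 2-fold in opposite directions were Spp1 (2.02-fold higher with ES, at least 4.24-fold lower with exercise) and Atp1b4 (log2 ratios of 1.68 and -1.10). Across 10092 genes, which are not independent replicates, the log2 ratios of ES and of exercise against ischemia correlated at r = 0.36. Simulated unchanged arrays gave 0.50 under either noise, which follows from equal noise on all arrays sharing the ischemia array. The spread of log2 ratios, as the median absolute deviation scaled to an SD, was 0.34 to 0.35 for pairs with ES and 0.19 to 0.25 for the others. The lower r therefore does not show that the treatments were less alike than unchanged arrays. The covariance of the ES and exercise ratios was 0.056, against 0.064 in the simulation with the wider noise and 0.029 with the narrower. The sign of that difference thus depended on the noise estimate.

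**Figure D3:**
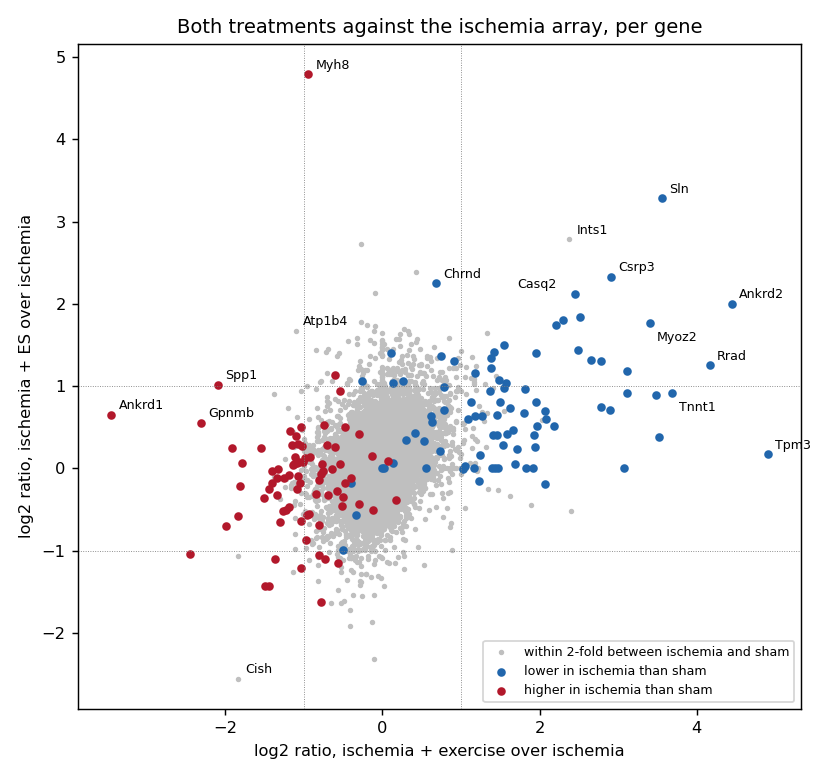
Each point is a gene, with the log2 ratio of exercise over ischemia on the x axis and of ES over ischemia on the y axis, from 1 array per group; blue and red mark genes past 2-fold lower and higher with ischemia than sham, and dotted lines mark 2-fold. Most blue genes lie to the right (65 of 87 past 2-fold with exercise) and fewer lie above the upper dotted line (28 of 87 with ES), while Myh8 stands apart at 4.79 on the ES axis.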

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

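All tests of explanations in this part were chosen after the results were seen.

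Opposite directions under the 2 treatments, on 1 array each, were flagged for 3 results. Spp1 was higher than ischemia with ES and lower with exercise, a gap of 3.10 in log2 ratio between ES and exercise (a lower bound, with exercise at the floor). Atp1b4 had a gap of 2.77. The median of the embryonic and regenerating myofibre list lay 1.43 higher with ES than with exercise. None of these differences was tested, since there are no replicates.

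The pattern with the largest list median was that of the slow-fibre genes, low with ischemia, back with exercise and partly higher with ES. Scaling between arrays is argued against, since under quantile or loess normalization the list median between ischemia and sham nearest to 0 was still -2.73. Another share of slow fibres in the piece of muscle sampled stays open for ischemia, exercise and ES and cannot be told apart from a response. The falls with ischemia were unequal, with log2 ratios from -3.31 to -1.59 over the slow-fibre genes without Tpm3. Their SD was 0.60, against a noise SD of 0.13 for a ratio of 2 arrays under the narrower noise (from sham and exercise). Unequal falls do not exclude a changed share, since other fibres may hold some of these transcripts too. On the ES array, a changed share alone would have each gene regain the same share of the gap between ischemia and exercise. The share regained differed 9.96-fold between genes (without Tpm3). It ran from 7.55% for Tnnt1 to 75.1% for Casq2, with Myl3 next highest at 37.8%, so the 9.96-fold rests on Casq2. Each share also rests on 1 probe set. It was 19.6% for Myh7, whose other probe set had log2 ratios against ischemia of 0.11 with ES and 4.02 with exercise. Probe sets of 1 gene thus disagreed too, so the unequal shares do not exclude a changed share of slow fibres on the ES array. A response of the fibres to ischemia and to exercise stays open as well, and was not tested, because the sources used here do not say which muscle or region was taken.

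The medians of macrophage and matrix genes were high with ischemia and with ES and lower with exercise. A lower share of muscle in the sampled piece, with the other cells in unchanged proportions, would raise the markers of every other cell type alike. Macrophage markers, however, exceeded endothelial markers by 0.88 in median log2 ratio between ischemia and sham (standard error 0.27). These values bear on that case only, and a piece with another mix of the other cells stays open. Standard errors in this part are taken over the genes of each list, as if independent, on 1 array per group. They hold no variation between animals or arrays. Tendon in the piece is argued against for the matrix genes of the ES array: between ES and exercise all 6 tendon markers had ratios below 0, 3 of them past 2-fold, and the difference of medians, tendon minus matrix, was -1.88 (standard error 0.33). It stays open for the ischemia array. The tendon median was higher with ischemia as that of the matrix genes was, and between exercise and ischemia it lay 0.83 above the latter (standard error 0.34), but the 6 members went both ways, from -0.78 to 0.82, and the difference was 0.54 with a floor at the 70th percentile. All 18 macrophage and all 6 tendon markers measured were above the floor on the sham array too. More macrophages and fibroblasts with ischemia, and fewer with exercise, remain a hypothesis that may also reflect where a single piece was cut or which animal it came from.

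The medians of embryonic, endothelial and interferon genes were higher on the ES array than on the ischemia array. Scaling is argued against, as the lowest of the 3 list medians under quantile or loess normalization was 0.73. Endothelial markers exceeded macrophage markers by 0.99 between ES and ischemia (standard error 0.23 over genes). For them this argues against a lower share of muscle with the other cells in unchanged proportions. Another mix of the other cells in the piece stays open. RNA quality cannot be told apart from ES: the actin 3' over 5' ratio was highest on that array (5.94). The GAPDH ratio was highest there too but differed less between arrays (1.26 with ES, 1.04 with ischemia). The positions of probe sets along transcripts, which would be needed to test an effect of RNA quality, were not used here. An effect of ES on the muscle, or damage and regeneration in the animal behind that array, therefore stays a hypothesis that these data could not separate.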

How the results depend on the processing

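None of the 50 list medians that stood apart and none of the 231 named ratios past 2-fold changed sign under any alternative run. For single ratios another floor or threshold cannot change the sign, so that check rests on the normalizations and the probe-set settings. Leaving out probe sets open to cross-hybridization moved 0 of 257 named ratios by more than the noise. Most named genes rest on probe sets without that mark, so their ratios could not change in this setting. Of the 66 list medians that did not stand apart, 18 changed sign, in 28 cases over the alternatives. The cause was not tested. Those with the largest size before or after were fast-fibre genes between ES and ischemia (0.19, under quantile normalization -0.001), neutrophil markers between ES and exercise (0.31, with a floor at the 30th percentile -0.08), and with a floor at the 70th percentile erythroid markers between exercise and ischemia (0.01 and -0.22) and immediate early genes between ES and ischemia (0.06 and -0.14). Quantile and loess normalization kept all 12 counts within 1.5 times. Of the 50 list medians, 46 stood apart under every alternative that was run on lists. Floor and threshold set how many genes are counted, by construction. The counts below are in the order: higher and lower with ischemia than sham, with ES than ischemia, with exercise than ischemia, and with ES than exercise; higher in both treatments, lower in both; moved back with ES, and with exercise. With a floor at the 30th percentile they were 251, 209, 448, 187, 306, 268, 548, 252, 91, 47, 120 and 234. With a floor at the 70th percentile they were 30, 50, 107, 48, 62, 35, 134, 63, 18, 5, 23 and 62, and the correlation of ES and exercise ratios was 0.39. With a 1.5-fold threshold they were 499, 322, 989, 476, 406, 428, 1057, 464, 175, 73, 238 and 409. With a 3-fold threshold they were 11, 32, 25, 9, 43, 11, 40, 27, 9, 1, 7 and 34. With the mean of all probe sets of a gene, 5 genes were lower in both treatments. More genes were lower than higher with ischemia, which turned with the floor at the 30th percentile and the 1.5-fold threshold, and more were higher than lower with exercise, which turned with the 1.5-fold threshold. Ratios of named genes moved by more than the noise for 18 of 257 with the floor at the 30th percentile, 79 of 226 with the floor at the 70th and 56 of 257 with the mean of probe sets. Of those past 2-fold, 48 of 200 with the floor at the 70th percentile, 32 of 231 with the mean of probe sets, 7 of 231 under quantile and 9 of 231 under loess normalization no longer were.

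Some list medians no longer stood apart; the cause was not tested. Between ES and exercise these were cytokines under quantile normalization (0.19) and with a floor at the 30th percentile (0.41), and lymphocyte markers under quantile (0.68) and loess normalization (0.67). Between exercise and ischemia, with a floor at the 70th percentile, they were mitochondrial gene regulators (0.076) and adipocyte markers (0.16). Other medians came to stand apart, and the cause was not tested there either. The heat shock list did so between ES and ischemia under quantile (0.27) and loess normalization (0.28), with a floor at the 30th (0.26) or the 70th percentile (0.26) and with the mean of probe sets (0.26). Between ES and exercise it was fibroblast markers under quantile normalization (0.28), Schwann cell markers with a floor at the 30th percentile (0.61) and mitochondrial gene regulators with the mean of probe sets (-0.19). The cytokine list had only 2 of its 10 measured members above the main floor on sham. With a floor at the 30th percentile it came to stand apart between ischemia and sham (0.40) and between exercise and ischemia (-0.33). Tendon markers did so between exercise and ischemia with a floor at the 70th percentile (-0.29), and the citrate cycle and respiratory chain between ischemia and sham with the mean of probe sets (-0.11).

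Added after seeing the data were the narrower simulation noise, whose values stand beside the wider, and the agreement of probe sets. Among counted genes with another probe set above the floor, the second went the same way for 29 of 29 (ischemia against sham), 52 of 60 (ES against ischemia), 34 of 38 (exercise against ischemia) and 77 of 82 (ES against exercise). Over all genes with another probe set, counted or not, this held for 61.4%, 67.1%, 59.7% and 66.6%. Leaving out genes with a probe set going the other way kept each of the 8 counts of the comparisons within 1.5 times, and the overlaps and the genes moved back were not counted again. Of 50 named ratios past 2-fold with another probe set above the floor, 18 had such a probe set within 2-fold or going the other way. Signals near the floor limit ratios of dim genes to bounds. No paired analysis was possible because each group had 1 array.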

Other observations

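All tests of explanations in this part were chosen after the results were seen.

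Measured against sham, the arrays of both treatments lay at very different distances. With exercise 26 genes were more than 2-fold higher than sham and 19 lower, while with ES 381 were higher and 107 lower. The 5S ribosomal RNA control probe set read 188 on the sham array, 155 on the ischemia array, 95.0 with ES and 99.8 with exercise. Probe sets with no gene symbol or with several, 3877 of them above the floor, also differed past 2-fold: 21 higher and 28 lower between ischemia and sham, 53 and 41 between ES and ischemia, 32 and 26 between exercise and ischemia, and 65 and 31 between ES and exercise.

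The 4 arrays can be split into pairs in 3 ways, which allows a count that does not rest on the ischemia array alone. With a response common to electrical stimulation and exercise, genes with both treated arrays at least 2-fold above or below both untreated arrays would outnumber those of the other splits if the response led away from sham. There were 6 such genes: Dbp, Ints1, Msmp and Osbp2 were higher with treatment, and Cish and Gadd45g lower; Msmp and Osbp2 are named after their values were seen. The split of sham and exercise against ischemia and ES held 59 genes apart, 28 higher and 31 lower with ischemia and ES, and the third split 2 (Rsad2 and Actg2, the latter named after its value was seen). A shared return toward sham does not enter this split, so the count of 6 does not argue against a common response. Of the 34 genes higher than ischemia with both treatments (at most 10 in simulated unchanged arrays with the wider noise), 21 had been lower with ischemia, and for these a common response cannot be told apart from a single ischemia array that differs from the other 3. Cish, which dampens cytokine and growth hormone signalling, and Dbp, an output gene of the circadian clock, may be worth a second look, the latter because the time of day at sampling is not given in the sources used here; with 6 genes and 1 array per group neither can be read as a treatment effect.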
